A study of Mus musculus with 5 samples.

How the data were processed

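Guide RNA abundance was measured in 5 libraries of a pooled CRISPR screen in mouse embryonic stem (ES) cells. In such a screen each cell carries a lentiviral guide RNA that directs Cas9 to a gene, and the share of reads on a guide reports how many cells carry it. There were 2 libraries of the plasmid pool before it entered cells and 1 library of transduced cells at each of days 5, 8 and 12. The cells carry the genotype label Ainv15(iNgn2 Tubb3::GFP) and were grown under Zeocin selection in ES cell medium, per the labels' protocols. The sample titles count the days from transduction while the treatment protocol counts the first time point from selection. The day numbers are therefore used as names of time points, except in the trend over days. There they enter as numbers, so its slopes per day rest on the count of the titles.

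The deposited values are raw read counts per guide, per the file headers and the values, which are whole numbers whose totals differ between libraries. The tools cutadapt, Bowtie and featureCounts and the genome build mm10 are named, without versions, per the submitters' processing notes. The reference the guide reads were matched to, and the mismatches allowed, are not given in the sources used here. Each library has 17820 guides, of which 16820 are assigned to 1682 genes at 10 guides per gene and 1000 are named as non-targeting controls. A guide sequence listed under 2 gene names had no reads. In the plasmid libraries 223 and 225 guides had 0 reads, and the 223 guides at 0 in both plasmid libraries had 0 reads in the cells too. Symbols were taken from a RefSeq gene table of the same build: 1661 matched directly and 21 by an older name, and gene coordinates are those of that table. Guide cut sites were not analysed here.

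Guides with fewer than 30 reads in either plasmid library were left out, which kept 15336 guides (14443 to genes and 893 non-targeting), 4 to 10 per gene with a median of 9. Counts were scaled to CPM values with TMM factors from edgeR 4.0.16 (R 4.3.3), and each guide's change was the log2 ratio of its scaled value plus a pseudocount of 1 to that of the reference plus 1. The reference was the mean of both plasmid libraries, or day 5 for the comparison of day 12 with day 5. A gene's score was the median over its guides. It was set against 100000 random sets of as many guides, drawn from the same of 10 bins of plasmid abundance, in a two-sided guide-set permutation test. Benjamini-Hochberg adjustment ran over the 1682 genes, with a threshold of 0.05. The smallest unadjusted p that these permutations can give is 2e-05. "Fell" and "rose" are used for genes past the threshold and are relative to the typical guide of the library.

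With 1 library per time point no test here has replicate cultures. The labels do not say whether the 3 time points are serial samples of 1 culture or come from separate or pooled wells, so a change from day 5 to day 12 may also hold a difference between wells. The permutation test compares these libraries, not conditions, and its p-values measure only whether the guides of a gene moved together against the spread of guides in the same libraries. The SD given beside a median is over the guides of that gene. A trend of each guide over days (plasmid at day 0) was tested with the quasi-likelihood test of edgeR on all 5 libraries, with 3 residual degrees of freedom. Its spread is that of the plasmid libraries and of departures from a straight course on the log scale.

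Before the data were examined, 17 gene lists, the comparisons, the alternatives and the rule for named genes were fixed. The lists cover the genes of the study's title and its design text, core and naive pluripotency, exit from naive pluripotency, the BTB family, general transcription, the MYC/MAX network, E2F/DP factors, the p53 family, growth-restraining factors, neural, mesoderm and muscle, endoderm and blood lineage factors, Hox genes, multicopy families, NF-Y subunits, and SWI/SNF, polycomb and other chromatin factors. A list's median was given as its percentile among 10000 random gene lists of the same size matched on plasmid abundance, which describes these libraries. A list was called apart when it lay outside the middle 95% of the random lists. The named genes were the 12 lowest and 8 highest medians at day 12 among called genes with 1 sign at days 5, 8 and 12. To these were added the 3 lowest and 3 highest called genes of day 12 against day 5, the genes of the study, Pou5f1, Nanog, Sox2, Esrrb, Klf4, Klf5, Sall4, Zfp42, Trp53, Tcf7l1, Myc, Max, Ctcf and Yy1, and the lowest and highest member of each list. The rule gave 59 genes. A further 17 lists were put together after the values were seen.

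The test was tried on simulated counts for the comparison of day 12 with the plasmid library, drawn for all 1682 genes with the spread of the non-targeting guides. It called 100% of 50 genes simulated at a log2 change of -2, 76% of 50 at -1, 74% of 50 at 1 and 100% of 50 at 2, and 5 of 1482 unchanged genes (0.337%). As many genes were simulated down as up, with unchanged guides centred at 0. In the real libraries 175 genes fell and 32 rose, and their guides enter the random sets. Real falls of a given size may therefore be called less often than simulated. Nor does the rate for unchanged genes carry over: 16 of 99 sets of 9 non-targeting guides were called higher at day 12. The trend test was tried on simulated counts for 15336 guides. It called 99.5% of 441 guides simulated at -0.2 log2 units per day and 60.8% of 426 at -0.1. It called 81.3% of 428 at 0.1, 100% of 434 at 0.2 and 0.463% of 13607 unchanged guides. In the simulation slow falls were thus found less often than slow rises. The simulated spread was a fixed value not estimated from these libraries. In the real libraries 43 of 893 non-targeting guides fell and 410 rose, so the rate for unchanged guides does not carry over to them.

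Alternatives were other scalings (total counts and the size factors of DESeq2 1.42.0), pseudocounts of 0.5 and 5, no guide filter or a minimum of 100 reads, the mean over guides, random sets not matched on abundance or drawn from the non-targeting guides, each gene without its most extreme guide, and each plasmid library left out. For the trend they were DESeq2, 2 or 4 groups in place of the day, and each library left out. A correction for guide GC content and random sets from guides of lineage and Hox genes were chosen after seeing the data. Statistics other than the trend and the scaling were computed with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3.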

Results

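The screen followed a lentiviral guide library against 1682 genes, mostly transcription factors and chromatin regulators, in mouse ES cells. Read totals were 3541896 and 1350234 in the plasmid libraries, 1063071 at day 5, 1082489 at day 8 and 1008492 at day 12. The kept guides had a median of 178 and 68 reads in plasmid libraries 1 and 2, and of 53, 53 and 47 reads at days 5, 8 and 12. The plasmid libraries differed by more than sampling noise, with a chi-square of 2.21 times its degrees of freedom over 15336 guides, and were counted as 2 libraries. Their log2 scaled counts had a Pearson correlation of 0.925 across guides, which are not independent replicates. Against plasmid library 1 the correlation across guides was 0.688 at day 5, 0.577 at day 8 and 0.517 at day 12. Of the kept guides to genes, 3, 49 and 93 had no reads at days 5, 8 and 12, and of the kept non-targeting guides 0 had none. Reads are not separate cells, so counts cover sequencing depth and not the number of cells sampled.

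The comparison of day 12 with the plasmid library asks which genes ES cells lost or gained guides for between the plasmid pool and day 12. It spans transduction and selection as well as growth in culture, and cannot tell these steps apart. Guides to 175 of 1682 genes fell and guides to 32 rose. The lowest median belonged to Ttf2, and the 12 lowest medians lay between -4.83 and -3.50. Guides to Ttf2, a transcription termination factor (chromosome 3, 100938860 to 100969700, mm10), had a median log2 change of -4.83 (SD 0.84, 8 of 8 guides below 0), and 3.52% of their plasmid abundance was left. Their summed reads were 276 at day 5, 74 at day 8 and 9 at day 12. The RNA polymerase II subunit genes Polr2g (-4.33) and Polr2c (-3.72), the chromatin remodeller Smarca5 (-4.23), the splicing factors Srsf1 (-4.08) and Snrpd1 (-3.50), the MYC partner Max (-4.04) and the replicative helicase gene Mcm2 (-3.89) were also among the 12 lowest. The others were the initiation factor gene Gtf2e2 (-3.72), the histone methyltransferase gene Ehmt1 (-3.63), Cnot2 of the CCR4-NOT deadenylase (-3.57) and Snapc1 of the small nuclear RNA activating complex (-3.52). All guides of these 12 genes lay below 0. Each had a permutation adjusted p of 0.000687, which comes from the smallest p the permutations can give. Ehmt1 passed in 13 of 14 alternatives, with a permutation adjusted p up to 0.262, and the others passed in every alternative in which they were tested. The pseudocount sets the size of such deep losses: over the alternatives the median of Ttf2 lay between -5.80 and -2.87, and that of Polr2g between -4.69 and -3.04.

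Among genes with 1 sign at all 3 days the 8 highest medians lay between 1.51 and 2.59. Guides to Kmt2d (2.13) and Ncoa3 (2.00) also rose to that range, with medians below 0 at day 5. Guides to Kdm5b, a histone H3 lysine demethylase gene (chromosome 1, 134560178 to 134632878), rose by a median of 2.59 (SD 0.45, 10 of 10 guides above 0), which is 6.00-fold. Guides to Trp53, the p53 tumour suppressor gene (chromosome 11, 69580348 to 69591873), rose by 1.79 (SD 0.58, 9 of 9 guides above 0), or 3.45-fold. The other 6 were the splicing factor gene Srsf6 (2.32), the Integrator subunit gene Ints12 (1.76), the ETS repressor gene Erf (1.68), the naive pluripotency regulator Prdm14 (1.58), the polycomb methyltransferase gene Ezh2 (1.54) and the corepressor gene Spen (1.51). The permutation adjusted p was 0.00109 for Prdm14 and 0.000687 for the other 7. The non-targeting guides also ended above the typical guide to a gene, with a median of 0.58 against -0.07. Of 99 sets of 9 non-targeting guides, 16 were called higher and 0 lower by the same test.

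**Figure D1:**
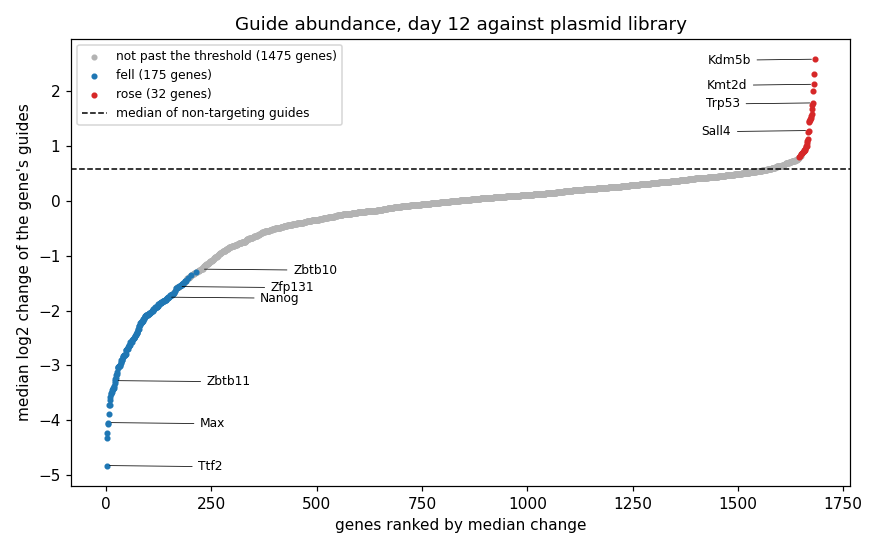
Median log2 change of each gene's guides at day 12 against the plasmid library (y axis), with the 1682 genes ranked on the x axis. Blue points are the 175 genes that fell, red points the 32 that rose and grey points the 1475 that did not pass the threshold; the dashed line is the median of the non-targeting guides, 0.58.

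The study's title names 2 genes, Zbtb11 and Zfp131, and its design text adds Zbtb10; all 3 code for zinc-finger proteins with a BTB domain. Guides to Zbtb11 (chromosome 16, 55971437 to 56008913) fell to a median log2 change of -3.28 at day 12 (SD 1.34, 8 of 8 guides below 0; permutation adjusted p = 0.000687), leaving 10.3% of their plasmid abundance. Guides to Zfp131 (chromosome 13, 119765186 to 119791477) had a median of -1.56 (SD 1.19, 8 of 8 guides below 0), or 33.8% of their plasmid abundance. Its permutation adjusted p of 0.0516 did not pass the threshold, and over the alternatives it ranged from 0.000118 to 0.541, with 6 of 14 past the threshold. Without plasmid library 2 it passed, with a median of -1.68 and a permutation adjusted p of 0.0377. Guides to Zbtb10 (chromosome 3, 9250567 to 9285333) had a median of -1.24 (SD 1.11, 8 of 8 guides below 0) with a permutation adjusted p of 0.125, which did not pass. Adjusted over the list alone, all 3 passed, with permutation adjusted p of 6.0e-05, 0.00963 and 0.0217. The study chose these genes, so neither that count nor the percentile of this list in any comparison is independent evidence. The list median of -1.56 lay at percentile 3.82 of random lists, inside the middle 95%; without plasmid library 1 it lay outside, at percentile 1.88.

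The core and naive pluripotency factors stood low as a group, with a median of -0.76 over 18 genes at percentile 0.11 of random lists. Guides to 3 of them fell: Nr0b1 (-2.09), Klf2 (-2.09) and Nanog (-1.76, SD 1.51, 10 of 10 guides below 0; permutation adjusted p = 0.0173). Guides to 2 rose, Prdm14 (1.58) and Sall4 (1.28, 9 of 9 guides above 0), although both genes belong to the pluripotency network. Over the alternatives Nr0b1 passed in 13 of 14 and Nanog in 12 of 13, with permutation adjusted p up to 0.276 and 0.0593. Adjusted over the list alone, 7 fell and 3 rose. Pou5f1, which codes for OCT4, had a median of -2.08 with 5 of 5 guides below 0, but with 5 guides the permutation adjusted p was 0.0753 and did not pass. It passed under 4 of 13 alternatives, no guide filter among them, and over these its permutation adjusted p ranged from 0.000118 to 0.161. Sox2 (-0.35), Esrrb (-0.16), Klf4 (-0.69), Klf5 (-1.15) and Zfp42 (-0.27) did not pass. With a minimum of 100 plasmid reads 6 members were left, and the list median of -0.31 lay at percentile 19.2.

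Factors of exit from naive pluripotency did not stand apart: the median over 13 genes was 0.09, at percentile 72.4, and 1 member, Etv5 (-1.68), fell, as it did adjusted over the list alone. Without plasmid library 1 the sign of the list median turned, to -0.098 at percentile 32.9. Tcf7l1, a repressor of the naive network, had the highest member median, 0.47, and did not pass. Among 39 BTB family genes the median was -0.07, at percentile 21.5; without plasmid library 2 it was 0.023, at percentile 59.6. Guides to Zbtb11 and Zbtb17 (-2.83) fell and guides to Zbtb2 (0.98) and Zbtb48 (0.90) rose, with the same counts adjusted over the list alone. Against random sets of non-targeting guides the call on Zbtb2 was one of the 2 lost among the named genes.

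General transcription and broadly required factors had the lowest median of the lists fixed beforehand with more than 3 genes, at -1.32 over 30 genes, below all 10000 random lists. Guides to 12 of them fell, among them Max, the NF-Y subunit gene Nfya (-3.0) and the insulator protein gene Ctcf (-2.65, 10 of 10 guides below 0), and guides to 0 rose. Nfya passed in 12 and Ctcf in 13 of 14 alternatives, with permutation adjusted p up to 0.0836 and 0.181. Adjusted over the list alone, 16 fell and 1 rose, Nfyc (0.66). Nfyc lay near the non-targeting median of 0.58 and passed over all genes in 0 of 14 alternatives. Yy1 (-0.87) and Myc (0.09) did not pass. Of the 3 NF-Y subunit genes, with a list median of -1.10 at percentile 3.98, guides to 1 fell, Nfya. Adjusted over the list alone, 2 fell and 1 rose, again Nfyc. The 25 SWI/SNF, polycomb and other chromatin factors had a median of -0.45 at percentile 0.38. Guides to 6 fell, with Smarcc1 (-2.70), a SWI/SNF core subunit gene, the lowest, and guides to 1 rose, Kdm5b; adjusted over the list alone, 7 fell and 1 rose. At day 8 this list, with a median of -0.18 at percentile 3.95, was inside the middle 95% of random lists.

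In the MYC/MAX network, 12 genes with a median of -0.0023 at percentile 47.5, guides to Max fell and no other member passed, over all genes or adjusted over the list alone. The highest member was Mxd1 (0.69). The 9 E2F/DP genes had a median of 0.06 at percentile 63.0, and at day 8 the sign turned, to -0.16 at percentile 19.0. None passed either adjustment, with E2f6 (-1.80) lowest and E2f4 (0.70) highest; without plasmid library 2 E2f4 passed, at 0.88 (permutation adjusted p = 0.0375, and 0.0375 to 0.653 over the alternatives). The p53 family had a median of 0.68 over 3 genes, at percentile 99.3, where Trp53 rose and Trp73 (0.45) was the lowest. That median is the value of Trp63, which did not pass, and lay near the non-targeting median of 0.58. The 15 growth-restraining factors, a list that also holds Trp53, had a median of 0.31 at percentile 98.4, below the non-targeting median of 0.58. In both lists Trp53 was the single call, over all genes and adjusted over the list alone. The growth-restraining list moved inside the middle 95% of random lists when either plasmid library was left out (median 0.27 both times), and lay at percentile 64.2 after the GC correction.

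The lineage lists and the Hox genes had medians above 0 and below the non-targeting median of 0.58, so their percentiles are relative to other genes and not to control guides. The 23 neural lineage factors had a median of 0.34 at percentile 99.9, the 16 mesoderm and muscle factors 0.23 at percentile 95.4, the 14 endoderm factors 0.12 at percentile 80.5, the 16 blood lineage factors 0.19 at percentile 89.0 and the 37 Hox genes 0.19 at percentile 96.1. No member of the 4 lineage lists passed, over all genes or adjusted over the list alone. The lowest and highest members were Neurog2 (-0.41) and Pax6 (0.66), Eomes (-0.18) and Gata4 (0.64), Onecut1 (-1.01) and Hhex (0.69), and Ikzf3 (-0.49) and Foxp3 (0.89). Among the Hox genes guides to Hoxa3 (0.79) rose over all genes and 0 members passed adjusted over the list alone; Hoxb2 (-0.84) was lowest. The call on Hoxa3 was kept in 9 of 14 alternatives, with a permutation adjusted p of 0.0263 to 0.384. Without plasmid library 2 the Hox list lay at percentile 99.6, outside the middle 95%. After the GC correction, chosen after seeing the data, the medians were 0.22 for the neural list (percentile 98.7), 0.15 for mesoderm and muscle (85.7), -0.020 for endoderm (46.1), 0.096 for blood (75.1) and 0.051 for the Hox genes (62.4). The neural list, outside the middle 95% before, stayed outside, and the sign of the endoderm median turned. The correction also took the BTB family to 0.072 (percentile 72.6), the MYC/MAX network to -0.13 (20.4) and the E2F/DP genes to 0.19 (89.0). Of the multicopy families 1 gene, Sry (0.03), was in the library, and it did not pass.

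**Figure D2:**
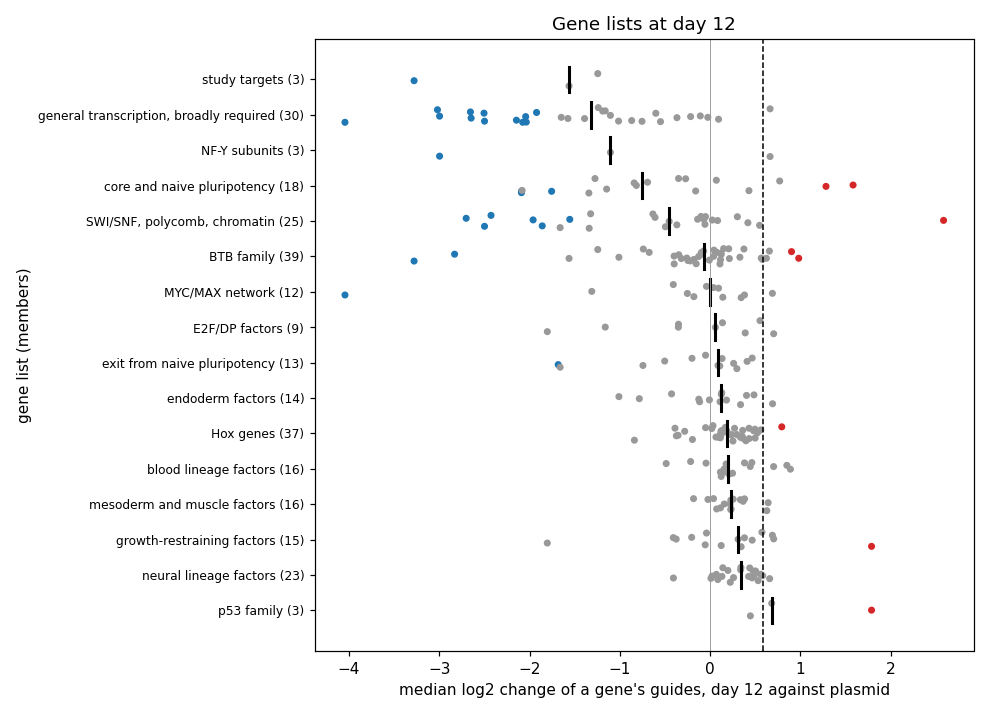
Median log2 change of each gene's guides at day 12 against the plasmid library (x axis) for 16 gene lists (y axis, members in parentheses). Points are genes, blue where guides fell, red where they rose and grey otherwise; black bars are list medians, from -1.56 for the genes of the study to 0.68 for the p53 family, and the dashed line is the non-targeting median of 0.58.

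The number of calls at day 12 depended on the reference guides and on the read filter. Against random sets of non-targeting guides 749 genes fell and 18 rose, and with at least 100 plasmid reads per guide, which left 4452 guides, 11 fell and 11 rose of 794 genes tested.

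The comparisons of days 5 and 8 with the plasmid library ask how early these changes were present. At day 5 guides to 98 genes fell and guides to 13 rose, and at day 8 guides to 162 fell and 25 rose. Guides to Smarca5 (-2.55), Polr2g (-2.52), Snapc1 (-2.30), Polr2c (-2.29) and Mcm2 (-2.22) had already fallen at day 5. Zbtb11 stood at -1.45 at day 5 (permutation adjusted p = 0.00561) and -2.73 at day 8 (permutation adjusted p = 0.000863), and Nanog at -1.18 and -1.65, both called. Zfp131 was at -0.87 and -1.30 and Zbtb10 at -0.20 and -0.56, with no call at either day. Pou5f1 did not pass at day 5 (-1.39) and fell at day 8 (-2.48). Guides to Trp53 were the highest at day 5, at 2.19 (SD 0.45, 9 of 9 guides above 0; permutation adjusted p = 0.00153), and at 2.39 at day 8. Guides to Ttf2 (-0.76) and Max (-0.72) did not pass at day 5 and fell at day 8, to -3.09 and -2.99. At day 5 the general transcription list had a median of -0.72, below all random lists, with 10 of 30 genes down. The pluripotency list had a median of -0.23 at percentile 1.28, with 1 of 18 down. The genes of the study had a median of -0.87 at percentile 2.39, outside the middle 95%, with 1 of 3 down. Above it lay the neural list (0.21, percentile 99.8, 1 gene up), the Hox genes (0.17, percentile 99.8, none up) and the p53 family (0.38, percentile 99.2, Trp53 up). The other fixed lists were inside. The medians of the neural list, the Hox genes and the p53 family were below the non-targeting median of 0.41 at day 5. At day 8 the general transcription (-1.12) and pluripotency (-0.44) lists lay below the middle 95%, and the p53 family (0.47), the neural list (0.29) and the Hox genes (0.25) above it. The medians of the lists above it were below the non-targeting median of 0.54 at day 8.

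Of the 98 genes that fell at day 5, 87 fell at day 12 too, and of the 13 that rose, 4 rose at day 12. Independent lists of these sizes would share 10.2 and 0.247 genes. In 10 simulations of unchanged cells against the same plasmid libraries, the lowest and the highest genes of each day, taken in these numbers whether called or not, shared a mean of 11.5 (SD 2.55) and 0.80 (SD 0.63). Because both comparisons use the same plasmid libraries, part of the excess may come from them. With plasmid library 1 as the reference for day 5 and library 2 for day 12, 81 genes fell at both days and 3 rose, where independent lists would share 8.84 and 0.147. The simulation drew the spread of guides separately for each day. Neither it nor the separate plasmid libraries cover effects that stay with a guide over the days, so the simulated values may be too low. Across non-targeting guides the GC slope was 0.126 log2 units per base at day 5 and 0.125 at day 12. Of the 175 genes that fell at day 12, 173 had a median below 0 at day 5, or 98.9%, against 52.4% among the lowest genes of the simulation. The 175 genes had a median of -1.02 at day 5, -1.91 at day 8 and -2.15 at day 12. Of the 32 that rose, 25 were above 0 at day 5, or 78.1% against 52.5% simulated, with medians of 0.32, 0.59 and 1.20. The simulation centred every guide at 0, while non-targeting guides had medians of 0.41, 0.54 and 0.58 at days 5, 8 and 12. The share above 0 at day 5 therefore does not show an early rise. The day 5 calls upward were few and unstable: without plasmid library 2 there were 8, against random sets of non-targeting guides 3, and after the GC correction 11, of which 3 were among the 13. Later upward calls also depended on the GC correction: 14 of 25 at day 8 and 23 of 32 at day 12 were kept.

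**Figure D3:**
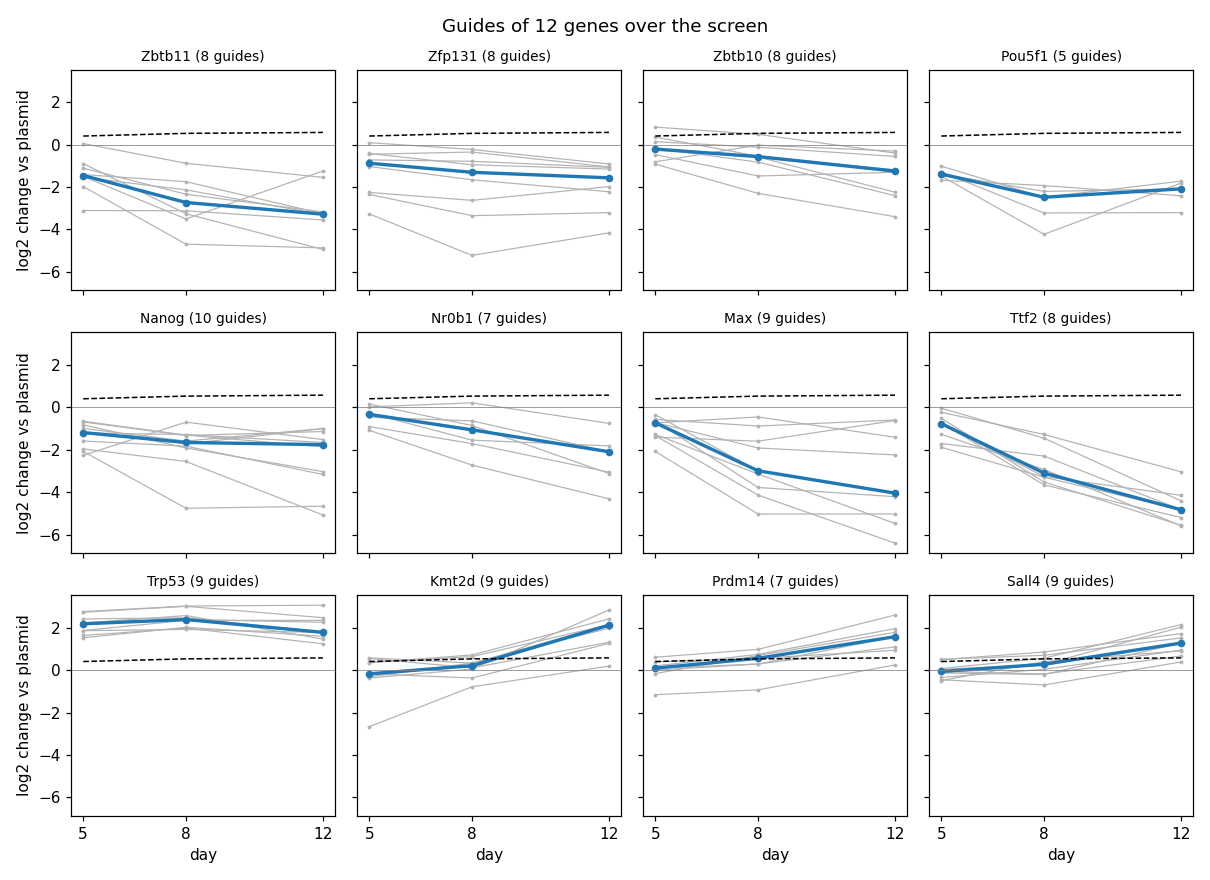
Log2 change against the plasmid library (y axis) at days 5, 8 and 12 (x axis) for the kept guides of 12 genes. Grey lines are guides, blue lines their median and dashed lines the median of the non-targeting guides; the blue line of Ttf2 goes from -0.76 to -4.83, that of Trp53 from 2.19 to 1.79 and that of Kmt2d from -0.17 to 2.13.

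The comparison of day 12 with day 5 asks which guides went on changing after the first time point, and does not use the plasmid libraries as the reference. Guides to 135 genes fell and guides to 30 rose. The lowest were Ttf2 (-3.83, 8 of 8 guides below 0), Max (-2.95) and the histone acetyltransferase gene Kat7 (-2.61, 8 of 8 guides below 0). The highest were Kmt2d, a histone H3 lysine 4 methyltransferase gene (2.08, 9 of 9 guides above 0; chromosome 15, 98831669 to 98874077), the nuclear receptor coactivator gene Ncoa3 (2.07, 10 of 10 guides above 0; chromosome 2, 165992637 to 166073242) and Kdm5b (1.78, 10 of 10 guides above 0). These 6 had a permutation adjusted p of 0.00146, from the smallest p the permutations can give. Guides to Zbtb11 fell further (-1.81, permutation adjusted p = 0.00224) and guides to Zbtb10 fell here (-1.39, 7 of 8 guides below 0; permutation adjusted p = 0.00864). Zfp131 had a median of -0.80 with a permutation adjusted p of 0.0800, which did not pass, and Nanog (-0.83, permutation adjusted p = 0.0609) and Pou5f1 (-0.71, permutation adjusted p = 0.323) did not pass either. Guides to Klf5 (-1.06) and Nr0b1 (-1.74) fell, and guides to Prdm14 (1.58) and Sall4 (1.29) rose. Trp53 had a median of -0.09 and did not pass.

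Over this interval the pluripotency list had a median of -0.43 at percentile 0.10, with 4 of 18 down and 2 up. The general transcription list (-0.56) and the chromatin list (-0.44) lay below all random lists, with 7 of 30 down and none up, and 6 of 25 down and 1 up. The genes of the study had a median of -1.39 at percentile 0.35, with 2 of 3 down. The growth-restraining factors (0.17, 1 gene down) and the Hox genes (0.11, no calls) lay just above the middle 95%. Neither exceeded the non-targeting median of 0.17 over this interval. Against random sets of non-targeting guides 392 genes fell and 28 rose, and with at least 100 plasmid reads per guide 8 fell and 8 rose.

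Guide by guide, a trend over the days asks how many single guides followed a course through the screen. In the quasi-likelihood test of edgeR 3534 of 15336 guides fell and 2761 rose. Among them were 10 of 10 guides to Nanog, 8 of 8 to Ttf2, 5 of 5 to Pou5f1, 7 of 8 to Zbtb11, 7 of 8 to Zfp131 and 5 of 8 to Zbtb10, all falling, and 2 of 8 to Sox2. Rising guides included 10 of 10 to Kdm5b, 8 of 10 to Ncoa3, 6 of 7 to Prdm14, 5 of 9 to Kmt2d, 5 of 9 to Sall4 and 4 of 9 to Trp53. Of the 893 non-targeting guides 43 fell and 410 rose, so the shares of rising guides for Kmt2d, Sall4 and Trp53 were not far from that of the controls. Without plasmid library 1 the counts were 2181 and 1405, and without plasmid library 2 they were 2480 and 1621.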

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

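The tests of explanations in this part were chosen after the results they bear on were seen. The non-targeting guides stand outside the gene comparisons, and they were not level: their median log2 change at day 12 against the plasmid library was 0.58. Guides to 106 lineage and Hox genes had a median of 0.24, which leaves a difference of 0.34 (bootstrap SD 0.03). At day 5 the difference was 0.26 (bootstrap SD 0.03), and from day 5 to day 12 it grew by 0.09 (bootstrap SD 0.03). Guide GC content went with the change, with a correlation across non-targeting guides of 0.324 at day 12, but non-targeting guides held fewer G and C bases (11.1 of 20) than the lineage and Hox guides (11.8). After subtracting the line fitted to the non-targeting guides the difference was 0.42 (bootstrap SD 0.04), and within 10 bins of plasmid abundance it was 0.36 (bootstrap SD 0.04), so neither property accounts for it. A cost of cutting the genome may set targeting guides back whatever the gene, a hypothesis that stays open: 4 kept guides lie within 2 mismatches of a guide to another gene, too few to compare guides with more than 1 site.

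Guides to Trp53 rose by day 5 (2.19) and no further by day 12 (1.79). Outgrowth of a few clones would raise single guides. When the highest gene at day 5 was picked on a random part of the guides of each gene, Trp53 was picked in 100 of 100 splits. Its other guides lay a mean of 1.66 above the non-targeting median (bootstrap SD 0.29), which argues against clones as the whole cause. A small further rise hidden by the scaling of the day 12 library stays open: the Trp53 median from day 5 to day 12 minus that of the non-targeting guides was -0.26, within 2 bootstrap SD (0.19 each) of 0. No biological explanation was tested.

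Guides to 19 genes rose at day 12 and between days 5 and 12 with no call at day 5: Cbfa2t2, Erf, Ezh2, Hdac8, Kdm5b, Kmt2c, Kmt2d, Nap1l2, Ncoa3, Ncoa6, Prdm14, Rarg, Rbm15, Rxra, Sall4, Spen, Srsf6, Tfap2c and Zbtb2. The genes were picked because they rose. Drift or a few outgrown clones would act on single guides, so guides not used to pick a gene would lie at the non-targeting median. In 100 random splits the 19 genes with the highest median of that interval were picked anew from all 1682, on a part of their guides, and on average 13.3 of them were among the genes above. Their other guides lay 0.99 above the non-targeting median (bootstrap SD 0.22), which argues against drift and clones as the whole cause. The GC content of their guides predicts a shift of -0.0034 (bootstrap SD 0.0059), against a median shift of 1.24 over the typical guide. Loss of these genes may favour ES cells in culture. The lack of a call at day 5 does not show that such an advantage began late. Day 5 medians of the 19 genes ran from -0.28 (Zbtb2) to 0.51 (Kdm5b), with the non-targeting median at 0.41. With 1 library at each time point a second screen is needed to separate an advantage from a property of the cells sampled. No biological explanation was tested.

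A test of day 12 against day 5, applied to the genes named by rule, marked those whose change differed between the days. Guides to these fell between day 5 and day 12: Ttf2 (-3.83), Max (-2.95), Kat7 (-2.61), Mcm2 (-2.09), Smarcc1 (-2.08), Srsf1 (-1.99), Polr2g (-1.85), Zbtb11 (-1.81), Smarca5 (-1.78), Cnot2 (-1.77), Snrpd1 (-1.77), Nr0b1 (-1.74), Gtf2e2 (-1.66), Ehmt1 (-1.60), Nfya (-1.43), E2f6 (-1.41), Zbtb10 (-1.39), Snapc1 (-1.30), Ctcf (-1.22) and Klf5 (-1.06). Guides to these rose between day 5 and day 12: Kmt2d (2.08), Ncoa3 (2.07), Kdm5b (1.78), Srsf6 (1.74), Prdm14 (1.58), Ezh2 (1.5), Sall4 (1.29), Erf (1.22), Spen (1.20), Ints12 (1.15) and Zbtb2 (0.85). Among all genes, 9 were called in both comparisons of day 12 with medians of opposite sign at days 5 and 12: Atm (0.03 and -1.70), Smarcb1 (0.08 and -1.86), Cbfa2t2 (-0.18 and 0.82), Kmt2c (-0.23 and 1.49), Kmt2d (-0.17 and 2.13), Ncoa3 (-0.27 and 2.00), Rarg (-0.12 and 1.44), Sall4 (-0.06 and 1.28) and Zbtb2 (-0.28 and 0.98). The day 5 medians of these 9 did not pass the threshold. Genes outside the naming rule were chosen after their values were seen.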

How the results depend on the processing

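The GC correction and the random sets from lineage and Hox guides were chosen after seeing the data. No paired analysis was possible because the plasmid libraries alone carry replicate numbers. Other scalings changed few calls in the gene test, since a common shift moves the random sets too: with total counts the median of guides to genes at day 12 moved by -0.11, and all 175 genes that fell kept the call. The trend of single guides has no such reference, and with total counts 3804 guides fell and 2182 rose, against 3534 and 2761. Against random sets of non-targeting guides, which sat higher, the genes that fell numbered 749, 628, 872 and 392 for day 12, day 5, day 8 and day 12 against day 5, and those that rose at days 12, 5 and 8 numbered 18, 3 and 5. Random sets from lineage and Hox guides gave 366 down at day 12 and 267 down for day 12 against day 5. With at least 100 plasmid reads, which left 794 genes and fewer guides each, genes down and up were 11 and 11, 2 and 2, 12 and 7, and 8 and 8 in that order. Without the most extreme guide, a conservative setting because the random sets keep theirs, they were 108 and 20 at day 12, 54 and 4 at day 5 and 62 and 17 for day 12 against day 5, and 10 rose at day 8. With the mean over guides 23 rose at day 5 and 43 at day 8. Leaving out a plasmid library gave 8 to 11 genes up at day 5, 2181 to 2480 falling and 1405 to 1621 rising guides in the trend, list medians of -1.68 to -1.59 for the genes of the study (percentile 1.88 without library 1, outside the middle 95%) and 0.19 to 0.27 for Hox genes, and 0.27 for the growth-restraining factors without either. List medians near 0 moved across it: without plasmid library 2 the MYC/MAX network stood at 0.010, and with total counts the exit factors at -0.024 and the E2F/DP genes at -0.050, with their percentiles inside the middle 95%. The trend had 1141 falling and 980 rising of 4452 guides with at least 100 plasmid reads, and 1772 rising with 2 groups in place of the day; DESeq2 gave 2886 and 2163. With the mean over guides the genes of the study (-1.97) and the Hox genes (0.17) moved outside the middle 95% of random lists and the growth-restraining factors (0.16) inside it. At day 8 the growth-restraining factors (0.053) and the chromatin list (-0.18) were inside it and the Hox genes (0.25) outside. With at least 100 plasmid reads the pluripotency list (-0.31, 6 genes) was inside, as were the growth-restraining factors (0.069) after the GC correction. The cause was not tested except where given. Of 59 named genes at day 12, 0 changed direction past the threshold under any alternative. Against non-targeting sets 15 gained and 2 lost a call, and 4 lost it without the most extreme guide. With at least 100 plasmid reads 27 named genes could be tested, and 5 lost the call. Not all of the 27 had a call to lose: Myc and Sry, for example, had none. Depth limits the size of deep losses: at day 12 1 read was worth 1.09 CPM, about the pseudocount.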

Other observations

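All gene groups in this part were put together after the values were seen, so their counts and percentiles at day 12 against the plasmid library describe these libraries and test nothing. Guides to 16 of 24 RNA polymerase subunit genes fell, with a list median of -2.25 below all random lists, as did guides to 9 of 17 Mediator genes (-1.75, below all random lists) and 6 of 13 TFIID subunit genes (-1.48, percentile 0.01). Guides to 8 of 8 MCM helicase genes fell (-2.09, percentile 0.02), as did guides to 4 of 5 SNAPc genes (-2.21, percentile 0.08) and 3 of 6 CCR4-NOT genes (-1.18, percentile 0.95). In 11 DNA damage and recombination genes guides to 1 fell at day 5 and to 7 at day 12, with list medians of -0.44 and -1.70; Atm was among the 7. Of 14 genes of the polycomb complex that holds MAX and PCGF6, guides to 1 fell at day 5 and to 6 at day 12, with list medians of -0.32 and -1.48.

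Upward, guides to 3 of 3 genes grouped as the KMT2C/KMT2D complex rose, with a list median of 1.49 at percentile 99.99, after -0.17 at day 5. All 3, Kmt2c and Kmt2d among them, were already in the 19 genes that rose with no call at day 5. The groups in this part share members. Of 4 KMT2 methyltransferase genes guides to 2 rose, again Kmt2c and Kmt2d, and to 1 fell. Of 6 nuclear receptor coactivator genes guides to 2 rose, Ncoa3 (2.00) and Ncoa6 (1.26). Guides to 2 of 6 retinoid receptor genes rose, Rarg (1.44) and Rxra (1.09). Prdm14 and its partner gene Cbfa2t2 (0.82) both rose. Of 9 PRC2 genes guides to 1 rose, Ezh2, while Eed (-1.03) and Suz12 (-0.63) did not pass. Of 10 histone deacetylase genes guides to 2 fell and to 1 rose, Hdac8 (0.91). The Fox family (37 genes, 0.22) and the Sox family (18 genes, 0.37) had 1 gene up each and none down, and lay at percentiles 99.2 and 99.9. Both medians were below the non-targeting median of 0.58.

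Guide GC content went with the change against the plasmid library from the first time point. Across non-targeting guides the slope was 0.126 log2 units per G or C base at day 5 and 0.125 at day 12, and between days 5 and 12 it was -0.0014. The log2 changes of non-targeting guides had an SD of 0.56, 0.59 and 0.70 at days 5, 8 and 12. A robust SD, from the median absolute deviation, was 0.44, 0.48 and 0.60. Counting error alone, from the median variance of a guide, gives 0.20, 0.19 and 0.20, which is to be set against the robust SD.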
